A study of Mus musculus with 6 samples.

How the data were processed

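Total RNA from the dissected lateral prostate of 12-month-old C57BL/6 mice was hybridised to Affymetrix mouse gene arrays, 1 array per sample, with 3 samples whose epithelium was Pten+/- with the IKK2ca allele and 3 whose epithelium was Pten+/- alone. Tissue was kept in a stabilising solution and homogenised and RNA was purified on columns, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, sets the arrays to one common distribution and summarises the probes of a probe set by median polish. It therefore hides any difference in total RNA between arrays, and compresses differences of dim and of very bright genes. The genome build is not given in the sources used here and no coordinates are printed. No detection calls were used here, so for a dim gene it is not known whether a value lies above background.

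Groups and replicate letters were taken from the sample titles. The design text speaks of 3 mice per group without tying each array to 1 animal in so many words. The p-values therefore set group differences against the spread between these samples, which may or may not be separate animals. The number of arrays limits the precision. An exact permutation test of 3 against 3 arrays has a smallest two-sided p of 0.1, and none was used.

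The table held 28815 probe sets. In the platform annotation 21780 listed 1 gene symbol, 1605 several and 5430 none, and genes were named from the first kind alone. Of the single-gene probe sets 21689 were matched to a current gene table by gene identifier and 91 kept the annotation's symbol, and 0 symbols changed. For 998 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used, leaving 19935 genes. No such gene had significant probe sets of opposite direction (0 genes). Several well-known genes, among them Pten, Ar, Nkx3-1 and C3, had no probe set listing that gene alone and were not analysed here.

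Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates or a filter on dim genes) and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 fold changes are IKK2ca minus Pten_het, with moderated standard errors on 4 residual and 4.29 prior degrees of freedom. Folds are 2 to the power of that difference, and no bound was set on folds near the low end of the range. The 33 gene lists (629 genes, 583 measured, 3 through an older symbol, 46 not measured), the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 measured members were compared with all other genes by limma's camera with an inter-gene correlation of 0.01, adjusted over 33 sets (32 lists and the leukocyte lists joined). Camera with the correlation estimated from the data and fry were alternatives. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes.

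The named genes were Pten, Ikbkb, Acta2 and Myh11, the 8 with the largest rise and the 8 with the largest fall among genes past the threshold whose groups did not overlap, leaving out clone-type names, and for the smooth muscle and NF-kB lists and each list past camera the 3 members with the largest change past the threshold, filled up by the smallest unadjusted p. For each other list 1 member was taken the same way. Further members named beside them, and the mesothelial genes, were chosen after their values were seen.

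Alternatives were filters on mean level at percentiles 25 and 50, median centring, renewed quantile normalization, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, the replicate letter as a block, each array left out in turn, unmoderated statistics, all probe sets and a threshold of 0.1. The procedure was tested on simulated data with the real genes' means and spreads, each gene drawn independently (3 against 3, 19935 genes, 50 changed per size). It recovered 10% of genes changed by 0.5 on the log2 scale, 74% at 1, 92% at 2 and 100% at 4, with 7 false calls among 145. Genes on the real arrays varied together, so these rates need not carry over to them. Camera, tested on a simulated fall of 1 in the smooth muscle list with independent genes, passed 1 of 33 sets, the shifted one. Figures were drawn with matplotlib 3.10.9.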

Results

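Gene expression was measured on whole-transcript microarrays in the lateral lobe of the mouse prostate, with 1 array per sample and 6 arrays in all. The mice were C57BL/6 and 12 months old. In 3 samples the epithelium was heterozygous for the tumour suppressor gene Pten and carried IKK2ca as a homozygous allele (IKK2ca/ca), and these are called IKK2ca A, B and C. In the other 3 samples the epithelium was heterozygous for Pten alone, and these are called Pten_het A, B and C. IKK2 is the kinase that releases NF-kB from its inhibitors and is encoded by Ikbkb. The tissue was not sorted, so each value is an average over epithelium, stroma and infiltrating cells. Median log2 expression per array lay between 5.66 and 5.78. The first principal component held 68.2% of the variance and placed the IKK2ca arrays at 28.3 to 41.8, Pten_het A and B at -44.4 and -45.5, and Pten_het C between the groups at -10.3.

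The comparison asked what the IKK2ca allele adds to a Pten heterozygous epithelium, with inflammation, smooth muscle and invasiveness as the topics that the series title names. Ikbkb itself (probe set 10577560) was higher in every IKK2ca array than in every Pten_het array. Its log2 expression was 9.29 ± 0.03 (SD, n = 3) in IKK2ca and 7.94 ± 0.16 (SD, n = 3) in Pten_het, a 2.56-fold difference (log2 fold change 1.35 ± 0.12 SE, adjusted p = 0.00135). Whether its probes read the IKK2ca transcript as well as the endogenous one is not stated in the sources used here. Pten had no probe set assigned to it alone and was not analysed here. Of 19935 genes tested, 2179 (10.9%) differed at an adjusted p under 0.05, 1012 of them higher and 1167 lower in IKK2ca. At least a 2-fold difference was reached by 409 of the higher and 452 of the lower genes, 861 in all, and by 559 and 544 genes without IKK2ca B and C and 546 and 408 without Pten_het A and B. The balance of higher and lower genes was not stable. Without IKK2ca A more genes were higher than lower (725 and 646, and 383 and 364 of at least 2-fold), as were more of those of at least 2-fold without Pten_het C (659 and 610) and with array weights (576 and 522). With array weights 3548 genes passed, and the lowest weights fell on IKK2ca A (0.558) and Pten_het C (0.598). The count of 2179 also depended on single arrays, and lay between 576 without Pten_het B and 3391 without Pten_het C, with 1371, 900 and 814 without IKK2ca A, B and C and 907 without Pten_het A. A per-gene t statistic without limma's moderation called 0 genes after adjustment (lowest adjusted p 0.063) and 4264 at an unadjusted p under 0.05, against 4991 for limma.

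The gene with the largest rise was Msln (probe set 10449000), which encodes mesothelin, a cell-surface glycoprotein. Its log2 expression was 11.86 ± 0.14 (SD, n = 3) in IKK2ca and 6.74 ± 0.60 (SD, n = 3) in Pten_het, 34.9-fold higher (log2 fold change 5.12 ± 0.27 SE, adjusted p = 0.000529). Ly6d, a surface protein of the Ly6 family, was 15.5-fold higher, and the neutrophil-attracting chemokine Cxcl5 and the GABA receptor subunit gene Gabrp were both 13.5-fold higher. Haptoglobin (Hp), an acute-phase protein that binds haemoglobin, was 12.1-fold higher (log2 fold change 3.60 ± 0.20 SE, adjusted p = 0.000529). The secreted glycoprotein gene Olfm4 was 11.1-fold and Clca3a2 10.4-fold higher. Sfrp4, a secreted Wnt-binding protein, was higher by 3.33 on the log2 scale (adjusted p = 0.0399), but the call was lost without any one of IKK2ca B, IKK2ca C, Pten_het A or Pten_het B (adjusted p = 0.123, 0.135, 0.137 and 0.151) and with an intensity-dependent prior (adjusted p = 0.110). Msln is also a marker of mesothelium, the lining of body cavities, and 4 other mesothelial genes were looked up after its value was seen. Upk3b (log2 fold change 0.17, adjusted p = 0.607), Lrrn4 (-0.06, adjusted p = 0.853) and Muc16 (-0.25, adjusted p = 0.316) did not pass the test, and Wt1 rose by 0.50 (adjusted p = 0.0359).

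The gene with the largest fall was Spink1 (probe set 10458704), a trypsin inhibitor of seminal fluid. It was at 3.44 ± 0.28 (SD, n = 3) in IKK2ca and at 8.27, 12.18 and 10.95 in Pten_het A, B and C, 130-fold lower (log2 fold change -7.03 ± 0.81 SE, adjusted p = 0.00322). Its IKK2ca mean stood at percentile 9.6 of the genes tested, near the low end of the array's range. The spermine-binding protein gene Sbp was 51.9-fold lower (adjusted p = 0.0144), a call lost without IKK2ca B, IKK2ca C or Pten_het B (adjusted p = 0.0512, 0.0630 and 0.0584) and with an intensity-dependent prior (0.0511). The protease inhibitor genes Wfdc3 and Spink5 were 47.2-fold and 29.7-fold lower. The lipase-related gene Pnliprp1 was 36.0-fold, the synaptotagmin gene Syt10 21.9-fold, the glycosyltransferase gene Abo 19.2-fold and Tcaf3 18.8-fold lower. Lack of overlap between the groups' arrays was part of the rule that chose these genes, so it is not a result.

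**Figure D1:**
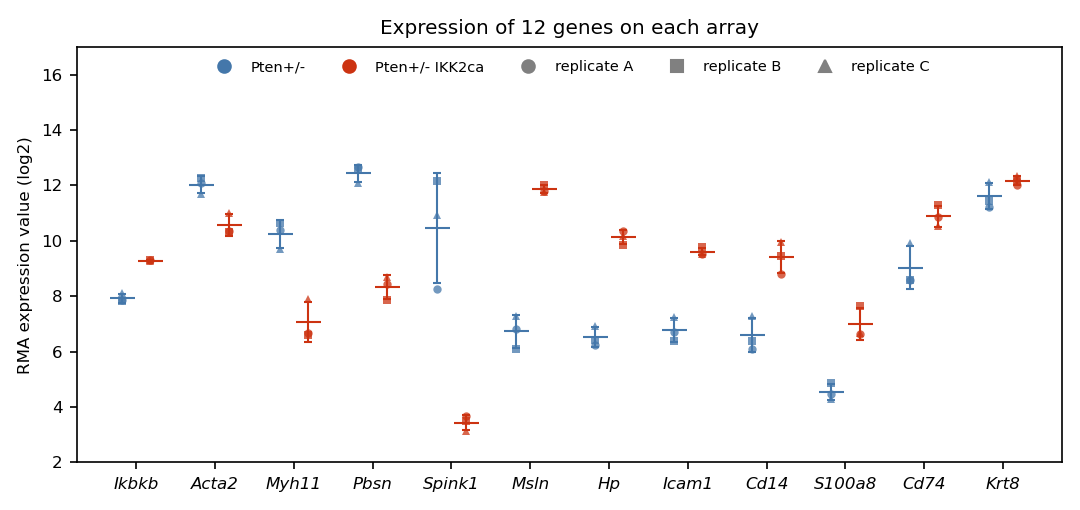
RMA expression (log2, vertical axis) of 12 genes on each of the 6 arrays, with Pten+/- in blue, Pten+/- IKK2ca in red and marker shapes for replicates A, B and C. Horizontal bars are group means and whiskers are 1 SD over 3 arrays. Ikbkb lay at 9.26 to 9.31 in IKK2ca and 7.83 to 8.12 in Pten_het. Pten_het C was the Pten_het array closest to IKK2ca for Ikbkb, Msln, Hp, Icam1, Cd14, Cd74, Acta2, Myh11 and Pbsn, but not for Spink1 or S100a8.

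Genes of the smooth muscle contractile apparatus fell together. Of 29 measured members of that list, 20 fell and 0 rose over all genes tested, and 23 fell when adjusted over the list alone. Myh11 (probe set 10437885), the smooth muscle myosin heavy chain, was 9.11-fold lower (log2 fold change -3.19 ± 0.37 SE, adjusted p = 0.00321), from 10.25 ± 0.50 (SD, n = 3) in Pten_het to 7.07 ± 0.73 (SD, n = 3) in IKK2ca. Acta2 (probe set 10467124), smooth muscle actin, was 2.75-fold lower (log2 fold change -1.46 ± 0.22 SE, adjusted p = 0.00790). The calmodulin-binding Pcp4 was 14.0-fold lower, and calponin (Cnn1) was 6.48-fold lower, a call lost without Pten_het B (adjusted p = 0.0535). Desmin (Des, -1.37), transgelin (Tagln, -1.38) and myosin light chain kinase (Mylk, -1.48) also fell on the log2 scale. Myocd, a coactivator of smooth muscle transcription, was at -0.44 and did not pass (adjusted p = 0.0891). The list's median log2 fold change was -1.02, and it lay below the other genes by limma's camera with a preset correlation of 0.01 (adjusted p = 2.86e-14) but not with an estimated correlation (adjusted p = 0.465). On the mean over its members, Pten_het C was at 0.26 relative to all 6 arrays, against 0.69 and 0.75 for Pten_het A and B and -0.70, -0.72 and -0.28 for IKK2ca A, B and C. Leaving out Pten_het B or A reduced the count of fallen members to 11 or 13.

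Most targets of NF-kB and some chemokine genes rose. Among 34 measured NF-kB targets 22 rose and 0 fell, and adjusted over the list alone 27 rose and 2 fell. Besides Cxcl5, the adhesion molecule Icam1 was 7.15-fold higher (log2 fold change 2.84 ± 0.21 SE, adjusted p = 0.00117). The inhibitor genes Nfkbia and Nfkbie rose by 1.84 and 2.19 on the log2 scale, and the cytokine genes Tnf and Il1b by 2.16 and 1.83. Tnip3 was 5.13-fold higher, a call lost without IKK2ca B, IKK2ca C, Pten_het A or Pten_het B (adjusted p = 0.0598, 0.0727, 0.0637 and 0.0796). The acute-phase gene Saa3 was at -1.48 and did not pass (adjusted p = 0.0890). The list's median was 1.09 (camera adjusted p = 4.46e-15, and adjusted p = 0.465 with an estimated correlation). Of 29 chemokine genes, which overlap with the NF-kB list in genes such as Cxcl5, 10 rose and 0 fell, and adjusted over the list alone 19 rose and 1 fell. Cxcl15 was 8.25-fold and the monocyte attractant Ccl3 5.27-fold higher, and the median was 0.71 (camera adjusted p = 3.34e-09, and adjusted p = 0.465 with an estimated correlation). In the complement and acute-phase list 5 of 20 members rose and 0 fell (adjusted over the list alone, 7 rose and 2 fell), among them Hp, ceruloplasmin (Cp, 5.05-fold) and complement factor B (Cfb, 3.17-fold). That list's camera adjusted p was 0.000976 and its adjusted p with an estimated correlation 0.465. Cfb lost the call without IKK2ca B, IKK2ca C, Pten_het A or Pten_het B (adjusted p = 0.0530, 0.0607, 0.0607 and 0.0538). Without Pten_het B, 12 NF-kB targets, 5 chemokine genes and 2 complement and acute-phase genes rose, and without Pten_het C 26, 15 and 9 did. The complement and acute-phase count was 2 without IKK2ca B or C and 3 without Pten_het A.

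Many, but not all, of the measured transcripts of myeloid leukocytes rose. Of 25 macrophage and monocyte genes 20 rose and 1 fell (adjusted over the list alone, 22 and 1), with a median of 1.46. The lipopolysaccharide co-receptor Cd14 was 7.04-fold higher (log2 fold change 2.82 ± 0.35 SE, adjusted p = 0.00436), and the C-type lectins Clec4d and Clec4n were 4.91-fold and 4.61-fold higher. The fallen member was Mertk, a receptor for apoptotic cells (-1.42). Of 17 neutrophil genes 10 rose and 0 fell, the same counts as when adjusted over the list alone, with a median of 1.12. S100a8, a calcium-binding alarmin, was 5.51-fold higher, the chemokine receptor Cxcr2 5.20-fold and Padi4 5.02-fold, whereas the granule genes Mpo (0.22), Elane (-0.19), Camp (0.02) and Ngp (-0.02) and the surface marker Ly6g (0.27) did not pass. Camera gave adjusted p = 5.36e-14 for macrophages and 1.23e-08 for neutrophils, and the adjusted p with an estimated correlation was 0.465 for each. The macrophage count fell to 6 without Pten_het B, to 9 without Pten_het A or IKK2ca C and to 12 without IKK2ca B, and the neutrophil count stayed at 9 or 10. On the mean over the macrophage genes Pten_het C stood at -0.21, against -0.93 and -0.86 for Pten_het A and B.

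Fewer genes passed in the other leukocyte lists. Among 18 T cell genes Cd8a (log2 fold change 0.75) and Cd8b1 (0.48) rose and 0 fell, and 5 rose when adjusted over the list alone. Cd3g, part of the T cell receptor complex, was at 1.29 (adjusted p = 0.0541). Cd8a lost its call without IKK2ca A or B or Pten_het A or B (highest adjusted p 0.0955, without Pten_het B). Cd8b1 lost it without any array but Pten_het C (highest adjusted p 0.172, without Pten_het B), with median centring (0.0534) and with an intensity-dependent prior (0.0524). Without Pten_het C 5 T cell genes rose. Among 18 B cell and plasma cell genes Bank1 fell by 1.84 on the log2 scale and 0 rose (camera adjusted p = 0.788), with the same counts over the list alone. Itgax, which encodes CD11c, rose by 1.23 among 15 dendritic cell genes, and was the one to rise over the list alone too. Its call was lost without IKK2ca B, IKK2ca C, Pten_het A or Pten_het B (highest adjusted p 0.0922, without Pten_het B). Of 14 natural killer and cytotoxic genes 0 passed, over the list alone as well, and Nkg7 was at 1.22 (adjusted p = 0.0828), Klrk1 at 0.48 (0.0787) and Ifng at 0.28 (0.186). Hpgds, a prostaglandin D synthase, rose by 1.02 among 10 mast cell genes (camera adjusted p = 0.495), a call that was kept without Pten_het C alone (highest adjusted p 0.128, without Pten_het B). Camera gave adjusted p = 0.00102 for T cells, 0.00915 for dendritic cells and 0.0305 for natural killer cells. With an estimated correlation the adjusted p was 0.593, 0.535 and 0.593. On the mean over the T cell and natural killer genes, IKK2ca C (-0.14 and -0.08) lay below Pten_het C (0.05 and 0.06) but above Pten_het A and B. On the dendritic genes IKK2ca A and Pten_het C were both at 0.04, above Pten_het A and B (-0.17 and -0.29). The dendritic call was lost without IKK2ca B or Pten_het B (camera adjusted p = 0.0722 and 0.0645), and the natural killer call without IKK2ca B, Pten_het A or Pten_het B (0.175, 0.0717 and 0.0851). Over all 117 leukocyte genes joined, 34 rose and 2 fell (41 and 2 over the list alone), with a median of 0.28, a camera adjusted p of 6.33e-11 and an adjusted p of 0.475 with an estimated correlation. By limma's fry the joined list gave an adjusted p of 0.134. The risen members of the joined list numbered 15, 18, 20 and 22 without Pten_het B, Pten_het A, IKK2ca C and IKK2ca B. Its median was 0.18 without IKK2ca B and 0.44 without IKK2ca C or Pten_het C.

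Of 8 MHC class II genes 4 rose and 0 fell, and 7 rose when adjusted over the list alone. The invariant chain Cd74 was 3.62-fold higher (log2 fold change 1.85 ± 0.36 SE, adjusted p = 0.0168), H2-Aa 2.71-fold and H2-Ab1 2.58-fold. The camera adjusted p was 1.69e-05 and the adjusted p with an estimated correlation 0.465. In the interferon response list 3 of 25 members rose and 0 fell, and 10 rose when adjusted over the list alone. The 3 were the immunoproteasome subunits Psmb8 (3.22-fold) and Psmb9 (2.78-fold) and the peptide transporter Tap1 (2.17-fold), all of which serve MHC class I peptide loading, whereas the antiviral genes Ifit1 (0.89), Mx1 (0.94), Rsad2 (0.85) and Oas1a (-0.06) did not pass. The list's median was 0.85, with a camera adjusted p of 1.67e-06 and an adjusted p of 0.561 with an estimated correlation. Without IKK2ca B the median was 0.35 and the camera adjusted p 0.00116. Its mean level was 1.01 on IKK2ca B, 0.06 and 0.07 on IKK2ca A and C, and 0.19 on Pten_het C. Without Pten_het C 8 MHC class II and 10 interferon response genes rose, and without Pten_het B 0 and 2 did. The MHC class II count was also 0 without IKK2ca A, IKK2ca B or Pten_het A and 2 without IKK2ca C. Cd74 and H2-Aa lost the call without IKK2ca A or B or Pten_het A or B (highest adjusted p 0.0763 and 0.0792), and H2-Ab1 and Tap1 without any array but Pten_het C (highest 0.129 and 0.135, without Pten_het B). Tap1 also lost it with an intensity-dependent prior (0.0519).

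**Figure D2:**
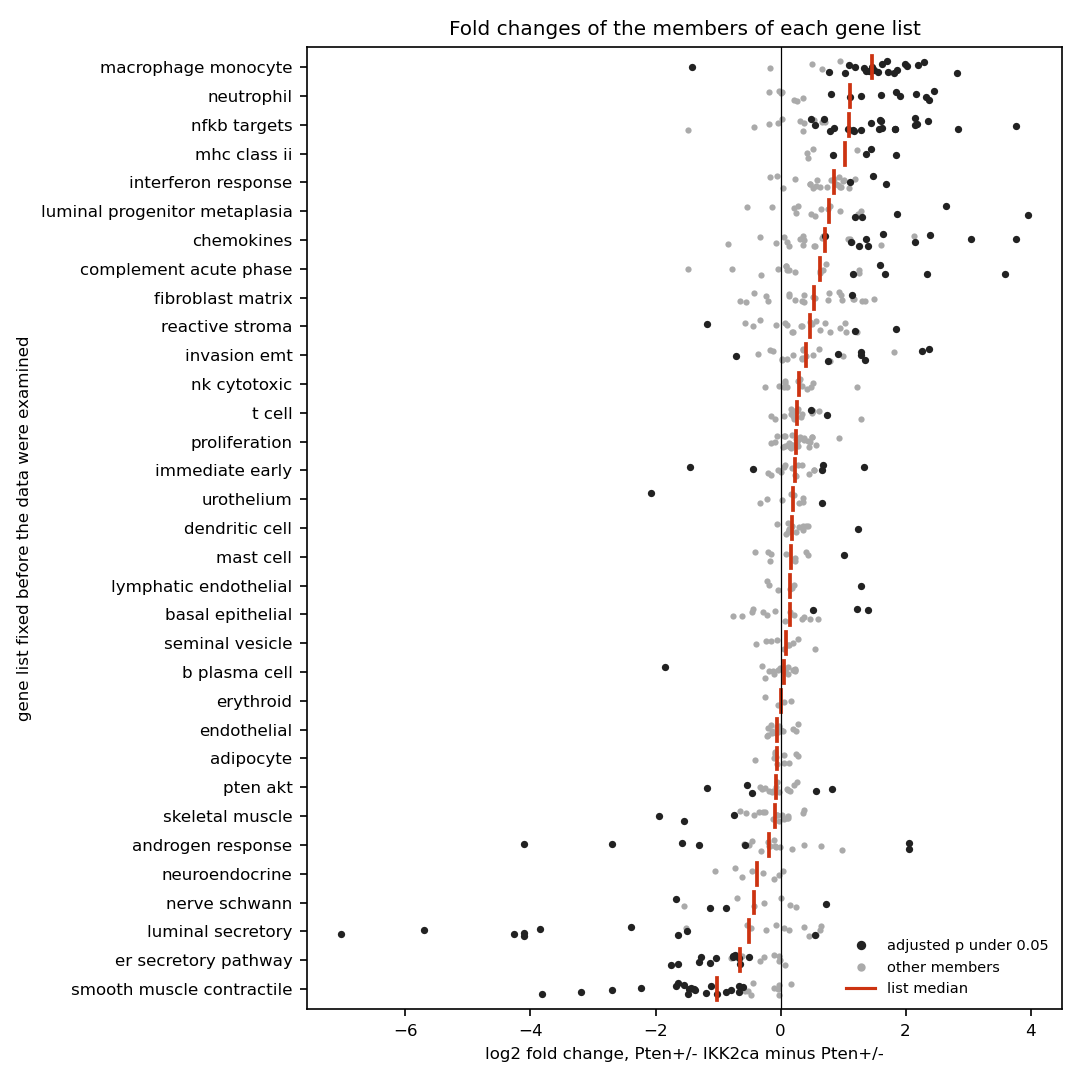
Log2 fold change (horizontal axis, Pten+/- IKK2ca minus Pten+/-) of each measured member of 33 gene lists (vertical axis), with members at an adjusted p under 0.05 in black, the others in grey and the list median as a red bar. The median was lowest for smooth muscle (-1.02) and highest for macrophages and monocytes (1.46), and the fallen luminal secretory members reached -7.03.

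Part of the secretory genes of luminal epithelial cells fell. Of 22 measured members 9 fell and 1 rose, and adjusted over the list alone 11 fell and 4 rose. Besides Spink1, Sbp and Abo, the androgen-driven secretory genes Pbsn (probasin, 17.1-fold lower, log2 fold change -4.10 ± 0.23 SE, adjusted p = 0.000529) and Tgm4 (-4.10) fell, as did Azgp1 (-3.85), Msmb (-1.64) and the homeobox gene Hoxb13 (-1.49). The risen member was the acid phosphatase gene Acpp (0.55), and with each array centred on its median 0 members rose and 10 fell. The keratin genes Krt8 and Krt18 and the epithelial gene Epcam, members of the same list, did not pass, at 0.57 (adjusted p = 0.149), -0.07 (0.770) and 0.14 (0.517). The list's median was -0.51 and its mean -1.54, with a camera adjusted p of 0.000871 and an adjusted p of 0.465 with an estimated correlation. Without IKK2ca C 6 members fell, without Pten_het C 6 rose and 9 fell with a median of -0.32, and 0 rose without IKK2ca B, IKK2ca C, Pten_het A or Pten_het B. Androgen-responsive genes went both ways. Of 22 measured, 5 fell and 2 rose (6 and 4 over the list alone), with Pbsn, the prostaglandin dehydrogenase Hpgd (-2.70) and Fkbp5 (-1.57) lower and the metalloreductase Steap4 and Pmepa1 (2.06 each) higher. The list's median was -0.18 and it did not pass camera (adjusted p = 0.0994), while fry gave an adjusted p of 0.00724. After renewed quantile normalization 4 of them fell, without Pten_het B 3 fell and 1 rose, and without Pten_het C 7 fell and 4 rose.

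Of 22 genes of the endoplasmic reticulum secretory pathway, among them chaperones and translocation factors, 12 fell and 0 rose, and 15 fell when adjusted over the list alone. Sdf2l1 was 3.36-fold lower (log2 fold change -1.75 ± 0.29 SE, adjusted p = 0.0104), Creld2 3.11-fold and the chaperone Hyou1 2.48-fold lower, and Hspa5 (BiP) fell by 0.76 on the log2 scale. The stress transcription factors Xbp1 (-0.02), Atf4 (0.07) and Ddit3 (0.00) did not pass. The list's median was -0.65, with a camera adjusted p of 1.23e-08 and an adjusted p of 0.465 with an estimated correlation. Its mean level on Pten_het C was 0.07, against 0.47 on each of Pten_het A and B. The count of fallen members was 3, 4, 5, 6 and 8 without Pten_het B, Pten_het A, IKK2ca B, IKK2ca A and IKK2ca C, and 16 without Pten_het C. Creld2 lost the call without IKK2ca A or B or Pten_het A or B (highest adjusted p 0.0847, without Pten_het B).

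Of 18 measured markers of luminal progenitors and metaplasia 5 rose and 0 fell, and 10 rose when adjusted over the list alone. With Ly6d these were the secreted protein gene Wfdc2 (6.23-fold), the simple-epithelium keratin Krt7 (3.63-fold), the transcription factor gene Sox2 (log2 fold change 1.31) and Prom1 (1.20). The median was 0.77, with a camera adjusted p of 6.92e-07 and an adjusted p of 0.468 with an estimated correlation. On this list Pten_het C was at 0.10, against -0.92 and -0.66 for Pten_het A and B, and without Pten_het C 12 members rose, while 3 rose without IKK2ca C or Pten_het B. Wfdc2 lost the call without IKK2ca C or Pten_het B (adjusted p = 0.0527 and 0.0512). Among 17 basal epithelial genes 3 rose and 0 fell (6 and 4 over the list alone). They included the keratins Krt17 (2.65-fold) and Krt14 (log2 fold change 1.23), while Krt5 (-0.28) and Trp63 (-0.46) did not pass, and the list did not pass camera (adjusted p = 0.177). Krt17 lost the call without IKK2ca A or C (adjusted p = 0.0651 and 0.0731), and 0 basal genes rose without IKK2ca C and 1 without IKK2ca A, Pten_het A or Pten_het B, and 2 with median centring. Without Pten_het A 1 basal gene fell, and without Pten_het C 2 did. Genes of the Pten and Akt pathway showed no common direction. Of 19, 2 rose (Ccnd1, 0.82, and Foxo3, 0.57) and 3 fell (Irs1, -1.18, Tsc2, -0.53, and Pik3ca, -0.45), with the same counts over the list alone and a camera adjusted p of 0.543. Without IKK2ca C or Pten_het A 0 of them passed, without IKK2ca B 2 and without Pten_het B 1. Without IKK2ca A 1 rose and 2 fell. The Irs1 call was lost without IKK2ca C or Pten_het A (adjusted p = 0.0582 and 0.0529). With median centring 2 fell.

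In the list of invasion and epithelial-mesenchymal transition genes 7 of 25 members rose and 1 fell (11 and 1 over the list alone). The integrin subunit Itgb6 was 5.21-fold higher (log2 fold change 2.38 ± 0.42 SE, adjusted p = 0.0120), and the matrix metalloproteinases Mmp3 and Mmp9 were 4.82-fold and 2.54-fold higher. Plau (1.28) and Mmp14 (1.28) rose too. Snai1 (0.10), Snai2 (0.02), Twist1 (0.21), Zeb1 (-0.36) and the mesenchymal cadherin Cdh2 (0.35) did not pass, and the fallen member was Twist2 (-0.72). The median was 0.41, with a camera adjusted p of 1.83e-05 and an adjusted p of 0.465 with an estimated correlation. Between 1 (without Pten_het B) and 4 (without IKK2ca B) members rose without any one of IKK2ca B, IKK2ca C, Pten_het A and Pten_het B. Without any array but Pten_het C 0 members fell. Itgb6 lost the call without Pten_het B (adjusted p = 0.0527), and Mmp9 without Pten_het A or B (0.0544 and 0.0672).

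Of 24 fibroblast matrix genes the peptidase inhibitor gene Pi16 rose (2.21-fold) and 0 fell (6 and 0 over the list alone), and the collagen gene Col3a1 (1.18) and Loxl1 (0.98) did not pass (adjusted p = 0.0520 and 0.0517). Of 23 reactive stroma genes Sfrp1 (3.58-fold) and the collagen gene Col12a1 (2.28-fold) rose, and the growth factor gene Fgf10 fell (2.26-fold lower), with 3 and 1 over the list alone. Of 29 proliferation genes 0 passed, over the list alone as well, and Pcna was at 0.48 (adjusted p = 0.0683), Mcm7 at 0.50 (0.0801), Mcm6 at 0.94 (0.0943) and Mki67 at 0.30 (0.630). The medians were 0.53, 0.48 and 0.25, the camera adjusted p 0.00249, 0.00867 and 0.00364, and the adjusted p with an estimated correlation 0.612, 0.612 and 0.638. These 3 calls were lost without IKK2ca B (camera adjusted p = 0.141, 0.194 and 0.0982), and that for proliferation also without Pten_het A (0.0880). Without IKK2ca B the medians were 0.32, 0.30 and 0.16. The fibroblast median was 0.87 without IKK2ca A, and that of proliferation was 0.14, 0.12 and 0.43 without Pten_het A, B and C. Without Pten_het C 8 fibroblast, 9 reactive stroma and 8 proliferation genes rose, and without Pten_het B 0 did in each list. Without IKK2ca A 5 fibroblast genes rose. Pi16, Sfrp1 and Col12a1 lost the call without IKK2ca C, Pten_het A or Pten_het B, and Pi16 and Sfrp1 also without IKK2ca B (highest adjusted p 0.156 for Pi16, 0.132 for Sfrp1 and 0.130 for Col12a1). Pi16 also lost it with median centring (0.0503), and Sfrp1 and Col12a1 with an intensity-dependent prior (0.0673 and 0.0519). On the mean over the proliferation genes Pten_het C stood at 0.28, against -0.36 and -0.30 for Pten_het A and B. IKK2ca A, B and C stood at 0.03, 0.29 and 0.06, so Pten_het C lay above IKK2ca A and C.

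**Figure D3:**
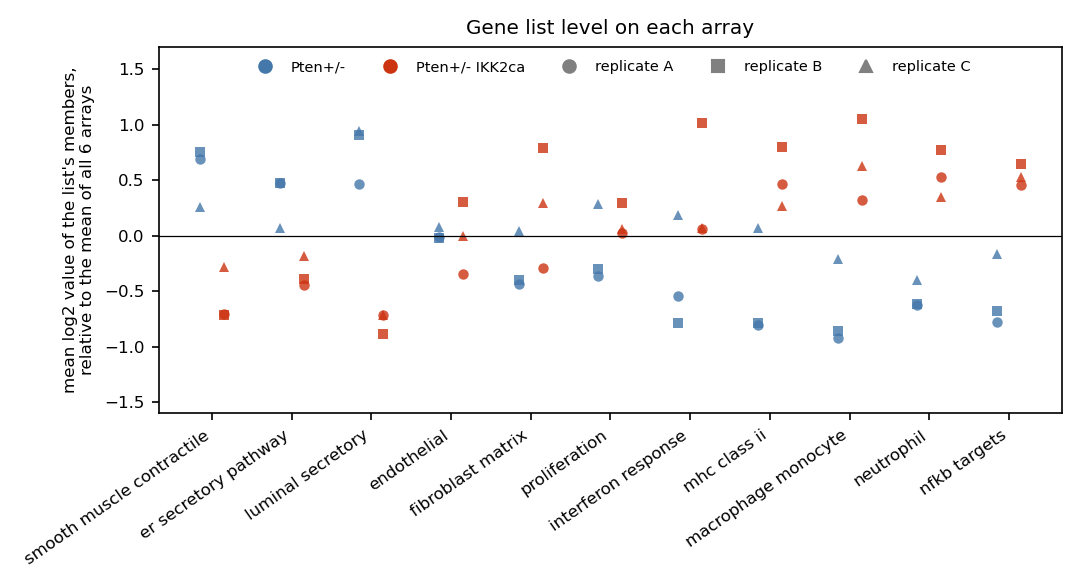
Mean log2 expression of the members of 11 gene lists on each array (vertical axis), relative to the mean of all 6 arrays, with Pten+/- in blue, Pten+/- IKK2ca in red and marker shapes for replicates A, B and C. For smooth muscle the Pten_het arrays lay at 0.26 to 0.75 and the IKK2ca arrays at -0.72 to -0.28, and for interferon response IKK2ca B stood at 1.01, apart from the other arrays.

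Lists of other cell types and neighbouring tissues, and of handling-sensitive genes, were examined in the same way. Of 15 endothelial genes 0 passed, over the list alone as well (median -0.05, camera adjusted p = 0.839), Egfl7 was at 0.28, and without IKK2ca B the list lay lower in IKK2ca (0.0392). Of 7 lymphatic endothelial genes Pdpn rose (1.29), also over the list alone, and the list did not pass (0.376). Seminal vesicle (10 genes, 0 passing, camera adjusted p = 0.947, Spinkl at -0.40) and adipocyte genes (11 genes, 0 passing, 0.990, Lipe at -0.41) showed no shift, and 4 erythroid genes, too few for camera, gave 0 passing (Alas2 at -0.25). Of 20 skeletal muscle genes 3 fell and 0 rose (6 and 0 over the list alone), namely Acta1 (3.84-fold lower), Mybpc1 (-1.54) and Tnnc2 (-0.74). The skeletal muscle list was at a camera adjusted p of 0.0507, and passed as lower in IKK2ca without IKK2ca A (0.0169) or Pten_het C (0.0192) and after median centring (0.0476) or renewed quantile normalization (0.0320). Its fallen members numbered 1 without IKK2ca C, Pten_het A or Pten_het B and 5 without Pten_het C. Of 11 nerve and Schwann cell genes 3 fell, including Uchl1 (3.20-fold lower) and the neurofilament gene Nefl (-1.14), and Cnp rose (0.73), with 6 and 1 over the list alone. The nerve list (camera adjusted p = 0.0775) passed as lower without IKK2ca B (0.0460) or Pten_het A (0.00528), and Uchl1 lost its call without IKK2ca A or C (0.0592 and 0.0695). Without IKK2ca C 0 nerve genes fell, and without IKK2ca A, IKK2ca B or Pten_het B 1 did. Of 8 neuroendocrine genes 0 passed (1 fell over the list alone), Scg2 was at -0.73 (adjusted p = 0.0526), and the list (camera adjusted p = 0.0640) passed as lower without IKK2ca A (0.0311), without Pten_het A (0.000147, with 4 genes falling) and after renewed quantile normalization (0.0390). Of 10 urothelial genes Upk1a fell (4.23-fold lower) and Upk1b rose (0.66), with 1 and 2 over the list alone and a camera adjusted p of 0.260. Of 19 immediate early genes 3 rose and 2 fell (4 and 2 over the list alone). Jun (1.34), Junb (0.68) and Socs3 (0.66) rose, Nr4a1 (2.74-fold lower) and the heat shock gene Hspa1a (-0.45) fell, and Fos (0.24) and Egr1 (-0.15) did not pass. That list was at a camera adjusted p of 0.0898, and at 0.0117 without Pten_het C, where 6 members rose. Without IKK2ca B, IKK2ca C, Pten_het A or Pten_het B 0 rose and 1 fell.

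Altogether 18 of 32 lists passed camera with the preset correlation, 15 higher and 3 lower in IKK2ca, and 0 of 32 passed with an estimated correlation, 1 of them (neutrophil) at an unadjusted p under 0.05. By fry 5 lists passed, 2 higher and 3 lower. The higher ones were NF-kB targets and neutrophils (fry adjusted p = 0.0370 and 0.0207). The lower ones were smooth muscle, luminal secretory and androgen-responsive genes (0.0370, 0.0173 and 0.00724). The preset-correlation test also passed between 9 and 23 lists in the other ways of dividing the 6 arrays into 3 and 3, each of which mixed arrays of both groups.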

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

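The tests of stromal dilution, neighbouring muscle, epithelial and luminal share, lobe mix and swapped labels were chosen after the results were seen, and those of other splits of the arrays and of mixed-in tissue before.

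Probe sets outside the gene comparison also differed from the Pten_het controls. In a fit over all 28815 probe sets, 82 without a listed gene were higher in IKK2ca and 61 lower, 26 and 26 of them by at least 2-fold. Among probe sets listing several genes 51 were higher and 31 lower.

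The smooth muscle list fell by a median of -1.02. If more epithelium or leukocytes had diluted the whole stroma, endothelial genes would have fallen by a like amount, but their median was -0.054 (SD 0.163 over members, not over arrays, and between -0.217 and 0.077 with each array left out). Their mean level was -0.35, 0.30 and 0.00 on IKK2ca A, B and C, and -0.01, -0.03 and 0.08 on Pten_het A, B and C. For IKK2ca B and C this argues against dilution of all stroma alike unless the endothelial share rose at the same time. For IKK2ca A, whose endothelial genes lay lower, the test cannot decide. Skeletal muscle and nerve genes joined had a median of -0.247 (SD 0.65 over members), so that more muscle-rich neighbouring tissue in the Pten_het dissections and a fall within the prostate cannot be told apart by this test, whose members spread too widely. A loss of smooth muscle cells and a lower content of contractile transcripts per cell in IKK2ca prostates both stay open and untested, since the arrays average over cells.

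Of the 22 luminal secretory genes, 9 fell, and these 9, picked out by their fall, had a median of -4.10 on the log2 scale. Fewer epithelial cells of every kind would have lowered basal epithelial genes as well, but the median of that list was 0.151 (SD 0.602 over members, between 0.103 and 0.287 with each array left out), which argues against such a loss as the whole cause of the 9 falls unless the basal share rose at the same time. Fewer luminal cells, with all luminal transcripts lowered alike, would have brought the whole list near -4.10, but its median was -0.507 (SD 2.3 over members, between -0.694 and -0.322 with each array left out). Since the 9 were picked by their fall, the whole list must lie above them, and this gap alone decides nothing. The members ran from -7.03 to 0.65, so they were not lowered alike. The keratins Krt8 (0.57) and Krt18 (-0.07), which this luminal list holds, and Epcam (0.14) did not fall with the 9. Whether they read luminal cells alone was not tested, so they do not settle how far luminal cells were lost. For 5 of the 9 fallen genes the range within the Pten_het arrays exceeded 25% of the fall (Spink1 3.9 and Sbp 4.44 on the log2 scale), and for the others it did not (Pbsn 0.581, Msmb 0.278, Azgp1 0.946 and Defb50 0.531), so a different mix of prostate lobes in the dissections and a change in luminal cells cannot be told apart, since a mix that differed steadily between the groups would leave narrow ranges too. A loss of luminal cells as part of the cause, or a change in their state with the IKK2ca allele, stays open and untested.

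Pten_het C lay between the groups, at -10.3 on the first principal component. It did not lie between them on every list. On the mean over the luminal secretory genes it stood at 0.94, against 0.47 and 0.91 for Pten_het A and B. IKK2ca A, B and C stood there at -0.71, -0.89 and -0.71. The Ikbkb value of Pten_het C was 1.134 below the lowest IKK2ca array on the log2 scale, against an SD of 0.0297 among those arrays. No IKK2ca array lay among the Pten_het arrays, which argues against a swap between the groups. Against a single wrong label the value counts to the extent that the probes read the IKK2ca transcript, which is unknown. IKK2ca tissue or RNA mixed into Pten_het C was tested on 107 genes at least 4-fold higher in IKK2ca. These passed the threshold in a fit of IKK2ca against Pten_het A and B, without Pten_het C. Under admixture they should have reached one common share of the difference in Pten_het C. The 10th and 90th percentiles of the shares were 6.14% and 46.0%, with Msln at 1.82% and Cd74 at 38.3%. That width was 0.399 as a fraction, against 0.159 between Pten_het A and B. This argues against admixture of average IKK2ca tissue as the whole cause. The median share was 23%, and Ikbkb was also higher in Pten_het C (8.12) than in Pten_het A and B (7.85 and 7.83). Admixture as part of the cause therefore stays open. More inflammation in that sample, or a dissection of other make-up, stays open and untested.

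With 6 arrays there are 10 ways of dividing them into 3 and 3, too few for a share under 0.05. Every division but the real one puts arrays of both groups on each side. A group difference then widens the spread and lowers the gene count, and part of it can remain in the lists. The others are therefore no clean comparison without a group difference. The real division gave 2179 genes and the highest of the others 0, so that 1 of 10 divisions gave as many. For genes changed at least 2-fold the real value was 861 and the highest other 0, again 1 of 10. For gene lists past camera the real value was 18 and the highest other 23, and 3 of 10 divisions gave at least 18.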

How the results depend on the processing

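Counts of list members without each array, the scalings of single lists and the name-stem families were chosen after the data were seen, and the other alternatives before. With median or percentile filters, centring, renewed quantile normalization, an intensity trend or averaged probe sets, between 2082 and 2402 genes passed, and in a fit over all probe sets 2058 probe sets did. Centring or renewed quantile normalization moved the counts of risen or fallen members of the lists by at most 1. Array weights gave 3548 genes, and a threshold of 0.10 gave 3411, as a looser threshold must. The unmoderated statistic gave 0 genes, and 0 of at least 2-fold (4264 at an unadjusted p under 0.05 against 4991 with limma), with fewer degrees of freedom. Leaving out 1 array gave 576 (without Pten_het B) to 3391 genes (without Pten_het C), and 408 to 1269 of at least 2-fold. Of the 576 and 3391 genes, 572 and 2115 were among the 2179, and 0 of the 2179 changed sign without any 1 array. With an estimated correlation 0 lists passed and with fry 5. The adjusted p with an estimated correlation was 0.465 for smooth muscle, 0.465 for NF-kB targets and 0.475 for leukocytes. Fry passed smooth muscle and NF-kB targets (adjusted p = 0.0370 for each) but not leukocytes (0.134). These 3 calls held under the other alternatives run on lists (the filters, scalings, trend, array weights, averaged probe sets, block and each array left out). Except where stated, the cause was not tested. The letters A, B and C gave no sign of pairing the arrays (correlations of same-letter deviations 0.14, -0.127 and -0.163, and not every array correlated best with its own letter). Deviations from means of 3 arrays are too few to exclude pairing. With the letter as a replicate block 1647 genes passed, 838 of at least 2-fold, and 20 lists, while Cd8b1, H2-Ab1 and Tap1 did not (adjusted p = 0.0962, 0.0570 and 0.0865). Of 64 named genes past the threshold 41 kept the call without any 1 array and 23 lost it without at least 1. Without detection calls, how far dim genes such as Spink1 in IKK2ca lie above background is unknown.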

Other observations

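Families of genes that share a name stem were examined after the results were seen. Of 309 stems with at least 8 measured genes, 17 passed camera with the preset correlation and 0 with an estimated correlation (adjusted p = 0.979 for each family below). Of 21 aldehyde dehydrogenase genes 7 fell, 0 rose and the others did not pass (median -0.16, camera adjusted p = 0.0489), with Aldh6a1 at -2.00, the mitochondrial acetaldehyde-oxidising Aldh2 at -1.61, Aldh7a1 at -1.14 and Aldh3a2 at -1.11. After renewed quantile normalization 6 fell and 1 rose, and without any one array but Pten_het C between 3 (without Pten_het B) and 5 (without IKK2ca A) fell. Genes of the Sec stem, most of which serve protein export from the endoplasmic reticulum, fell in 9 of 28 cases and rose in 0 (median -0.37, camera adjusted p = 0.00234). The coat proteins of export vesicles Sec24a (-0.84), Sec24d (-0.82) and Sec31a (-0.73) were among them, as were Sec61a1 and Sec61b, which the endoplasmic reticulum list also holds, and Sec14l4 (-0.82), a lipid-binding protein that shares the stem alone. The Sec count was 12 without Pten_het C, and between 1 (without Pten_het B) and 5 (without IKK2ca A) without any other array.

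On the immune side, 5 of 9 Schlafen genes rose and 0 fell (median 0.94, camera adjusted p = 0.00177), with Slfn4 at 2.30 on the log2 scale, Slfn2 at 1.31 and Slfn1 at 1.27. Toll-like receptor genes rose in 3 of 10 cases and fell in 0 (median 0.49, camera adjusted p = 0.00373), namely Tlr2 (1.44), Tlr13 (1.27) and Tlr1 (0.88), and in 2 after renewed quantile normalization. Of 8 colony-stimulating factor and receptor genes 4 rose and 0 fell (median 0.78, camera adjusted p = 0.00177), with Csf1, the growth factor of macrophages, at 1.16 and the receptor genes Csf3r and Csf1r, both also in the leukocyte lists, at 2.17 and 1.03. Without any one array but Pten_het C the counts of risen genes were 0 to 2 for Slfn, 0 to 2 for Tlr and 1 to 2 for Csf, and without Pten_het C they were 7, 5 and 6.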
